A study of Mus musculus with 3 samples.

How the data were processed

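The series compared miRNAs in exosomes from mouse bone-marrow MSCs kept in normoxia (N-Exo), hypoxia (H-Exo) or hypoxia with GW4869 (H+G-Exo) for 24 h. Per the labels' protocols, exosomes were pelleted by ultracentrifugation from medium cleared of cells, debris and larger vesicles, and the RNA was extracted with TRIzol and labelled with Cy3. These protocols name a kit that amplifies cRNA and one that makes cDNA, neither usual for a miRNA array, so how the hybridized material was labelled is uncertain. The design text speaks of 3 samples for each kind of exosome, while 1 array per group was analysed here, and the sources used here do not say whether the RNA of several samples was pooled. Groups were taken from the treatment given in the labels.

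Per the file headers, the authors scanned the 3 one-colour arrays and quantified them with Agilent Feature Extraction 10.7.1.1, and all 3 share 1 slide and 1 scan time, so slide and scan did not differ between the groups. The deposited files hold intensity values per spot. The main column is the processed intensity, from which the software had subtracted the background, and it can be below 0. No scaling between arrays had been applied in those files. The software's total intensity per miRNA, set to 0.1 where a miRNA was not detected, was used only as an alternative. The deposited value table of the series was read as log2 values. Over its values above the lowest, the Pearson correlation across miRNAs with the log2 of the sum of a miRNA's probes was 0.982 in N-Exo, 0.998 in H-Exo and 0.988 in H+G-Exo, against 0.457, 0.481 and 0.385 with the unlogged sum. Its columns share their mean and maximum, as quantile normalization gives, and have medians of -3.32, -3.00 and -3.30, and the method of its normalization is not given in the sources used here. Each column is 1 array, so it has no direction between groups. No sample of another series was used.

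Each array had 58594 spots, of which 2164 were control spots and were left out of all comparisons. The 56430 miRNA spots held 4415 probes for 1881 mouse miRNAs, with 7 to 30 spots per probe and 1 to 4 probes per miRNA. Spots marked by the software as non-uniform or population outliers were left out, 1568 in N-Exo, 1369 in H-Exo and 1466 in H+G-Exo, and 0 spots were saturated. The median coefficient of variation over the spots of a detected probe was 13.5%, 14.0% and 13.4%.

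The mean processed signal over the spots of a probe was divided by the array's 75th percentile over the probes detected on all 3 arrays, which was 417.3 in N-Exo, 235.0 in H-Exo and 468.9 in H+G-Exo. A probe counted as detected where more than 50% of its spots were well above background by the software's flag. Scaled signals under 0.0653, the highest of the 3 arrays' lowest detected signals, were raised to that floor before log2 was taken, so a fold against a signal under the floor is understated. A miRNA took the value of its brightest probe. Where several probes of a called miRNA were detected, their differences had opposite signs for 0 of 64 miRNAs in H-Exo against N-Exo, 5 of 147 in H+G-Exo against H-Exo and 4 of 217 in H+G-Exo against N-Exo. Near-identical mature sequences, such as those of the let-7 family, miR-23a and miR-23b or miR-27a and miR-27b, can share signal on such probes, so their separate values are uncertain. Coordinates are those of the probe matches in the array files, which use the mm9 build, and the files name no exon, intron or UTR. They are given with the lower position first, some span 1 base fewer than the probe, and the files do not say whether counting starts at 0 or 1, so an end may be off by 1 base. They were not checked against a genome here.

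With 1 array per group no test was possible. By rules fixed before the data were examined, a miRNA rose or fell if it was detected on both arrays, differed at least 2-fold, and differed by more than 2 times the standard error over its spots, which covers technical error within an array only. The number of arrays limits the precision of every comparison. A miRNA detected on 1 of the 2 arrays has a fold given as a lower bound: its scaled signal there over the higher of its own signal and the lowest detected signal on the other array. Such a bound holds under the main scaling only. The named miRNAs were, in every comparison, miR-210-3p and miR-210-5p, the 10 largest rises and 10 largest falls, the 5 largest bounds each way, up to 4 members of each fixed list with the largest difference, and the 10 brightest of each array. In the lists that overlap, a miRNA counts under each.

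There were 24 lists, fixed before the data were examined: hypoxia-responsive, angiogenesis-related, cardiac protection or repair, mesenchymal and fibroblast, p53-linked, inflammation-linked and bone, cartilage and fat differentiation miRNAs, the let-7, miR-15/16, miR-29 and miR-30 families, the miR-17~92, miR-232724, Dlk1-Dio3, Sfmbt2 and pluripotency clusters, markers of blood cells, endothelium, muscle and heart, epithelium and neurons, serum and liver miRNAs, and 2 technical lists, of GC-rich miRNAs often bright on arrays and of miRNAs numbered 3000 or above. A list's median runs over its members detected on at least 1 of the 2 arrays, with an undetected side at the floor. Its percentile among 10000 random lists of the same size, matched on mean signal, describes these arrays and is no test between conditions. The random lists were not matched on GC content or on whether a miRNA was numbered 3000 or above. Lists share members, so their medians are not independent.

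The calls were tested on simulated arrays of the 1881 miRNAs, made from the second array of each comparison and its spot errors, with 200 miRNAs changed. Of those changed 3-fold, 89% were called or given a bound of at least 2-fold in the right direction in H-Exo against N-Exo, 92% in H+G-Exo against H-Exo and 88% in H+G-Exo against N-Exo. Of those changed 1.5-fold, 1%, 0% and 1% were called, and of the unchanged ones 0 in each. The simulated arrays differed only by spot error and the changes put in. These shares therefore leave out differences between real arrays in input, labelling or scaling, and give no rate of false calls for the real comparisons. Alternatives were 4 other scalings, other background corrections, probe summaries, detection rules, floors and thresholds, and the deposited value table, 19 in all planned before the data were examined. A further 3 were chosen after seeing the data: scaling by the labelling spike-in probes, scaling by the hybridization spike-in probes, and a total per miRNA recomputed from its probes. The work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the normexp background correction with an offset of 50. A list of messenger RNAs of hypoxia had been set aside for an array with such probes, and was not used, as the arrays held miRNA probes.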

Results

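Exosomes are small vesicles that cells release into their medium. They were collected from cultured mesenchymal stem cells (MSCs), the adherent stromal cells grown out of mouse bone marrow, and their RNA was hybridized to mouse microRNA (miRNA) arrays. The cells had been kept for 24 h in normoxia (N-Exo), in hypoxia (H-Exo) or in hypoxia with GW4869 (H+G-Exo), a compound that inhibits neutral sphingomyelinase, an enzyme of exosome formation. Each group was 1 array, so no difference below has a replicate check and no p-value could be given. A value written with ± carries the SD over the replicate spots of 1 probe on 1 array, which is technical error only. Signals are scaled, that is, divided by the 75th percentile of the array, and fold changes compare scaled signals.

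Each array held probes for 1881 mouse miRNAs. The probes detected 685 miRNAs in N-Exo, 586 in H-Exo and 675 in H+G-Exo. miR-1224-5p gave the brightest scaled signal on all 3 arrays, 210.3 in N-Exo, 424.4 in H-Exo and 422.3 in H+G-Exo. The other miRNAs numbered below 3000 among the 10 brightest of N-Exo were miR-21a-5p, abundant in most stromal cells, at 190.4 ± 15.4, miR-125b-5p at 69.0 ± 1.79, let-7b-5p at 63.1 ± 2.31 and let-7c-5p at 59.97 ± 2.61. miR-21a-5p was the one of these 4 left among the 10 brightest of H-Exo, at 81.0 ± 4.11. In H+G-Exo none of the 4 was among the 10 brightest, which included miR-5126 at 137.2 ± 1.67, miR-6769b-5p at 128.3 ± 3.49, miR-8110 at 105.9 ± 3.12, miR-7036a-5p at 86.7 ± 2.77, miR-3473b at 60.5 ± 1.02 and miR-2137 at 54.2 ± 1.92. miR-3963, miR-6366 and miR-6931-5p were among the 10 brightest on every array, and miR-211-3p only in H-Exo, at 52.9 ± 0.749. miRNAs numbered 3000 or above, annotated late and in part GC-rich sequences that arrays show brightly, held 47.3% of the miRNA signal in N-Exo, 56.0% in H-Exo and 56.8% in H+G-Exo. The control probes are given as unscaled medians over 40 spots. Those named hur_2, whose target is not given in the sources used here, read 339621 in N-Exo, 175477 in H-Exo and 141565 in H+G-Exo, while the hybridization spike-in dmr_6 read 2084, 2100.2 and 2242. Of the labelling spike-ins, dmr_285 read 2316, 1356 and 1995, and dmr_31a 1744, 1530 and 1627, so both of these read lower in H-Exo than in N-Exo.

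miR-210-3p, the miRNA best known to be induced by hypoxia through hypoxia-inducible factor, was detected on every array. Its scaled signal was 7.51 ± 0.339 in N-Exo, 13.2 ± 0.443 in H-Exo and 6.17 ± 0.243 in H+G-Exo, over 15 spots each. It was 1.76-fold higher in H-Exo than in N-Exo, short of the 2-fold rule, and 2.14-fold lower in H+G-Exo than in H-Exo, which passed it. Its probe TCAGCCGCTGTCACAC matched chromosome 7 from 148407355 to 148407369 of the mm9 genome build, as the array design lists it. The other arm, miR-210-5p (chromosome 7, 148407320 to 148407331), was not well above background on any array. Before scaling, the miR-210-3p signal was 3133 in N-Exo, 3108 in H-Exo and 2894 in H+G-Exo, so its difference between the groups came with the scaling: H-Exo lay between 0.977-fold of N-Exo with hybridization spike-in scaling and 2.15-fold with quantile normalization. The median of all 582 miRNAs measured in both was 0.34 higher in H-Exo on the log2 scale, and miR-210-3p lay 0.47 above that median, at the 90.9th percentile of those miRNAs.

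**Figure D1:**
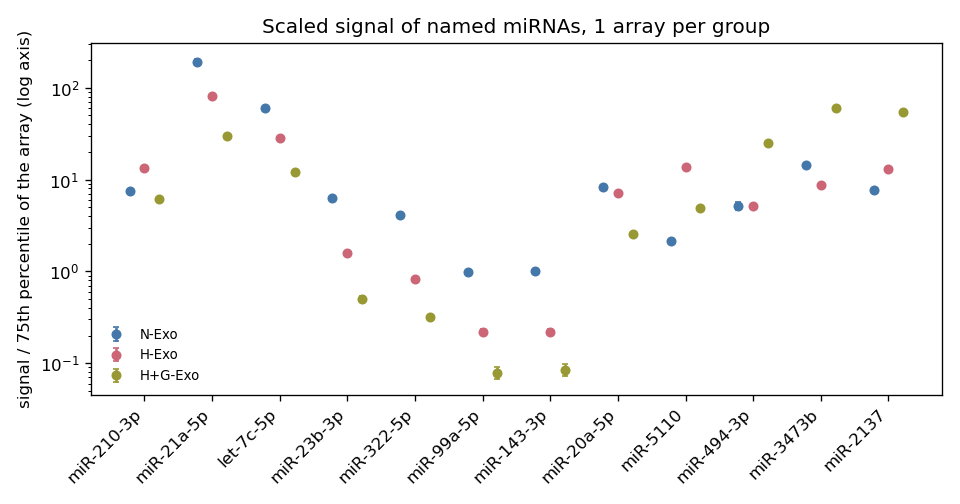
Scaled signal of 12 miRNAs (log axis, signal divided by the array's 75th percentile) in N-Exo, H-Exo and H+G-Exo. Each point is 1 array and each bar the SD over its replicate spots. miR-21a-5p, let-7c-5p, miR-23b-3p, miR-322-5p, miR-99a-5p and miR-143-3p stepped down from N-Exo to H-Exo to H+G-Exo, while miR-210-3p was highest in H-Exo at 13.2.

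The first comparison, of H-Exo with N-Exo, asked which exosomal miRNAs differed after hypoxia. Of 21 measured miRNAs on the fixed list of mesenchymal and fibroblast miRNAs, several of which are also on other lists, 13 fell in H-Exo. miR-99a-5p fell from 0.995 ± 0.0331 to 0.217 ± 0.0161, a 4.59-fold drop, and miR-143-3p, which supports the contractile smooth muscle state, fell 4.58-fold, from 0.999 ± 0.0532 to 0.218 ± 0.0168. miR-21a-5p fell 2.35-fold, and the let-7 family members let-7i-5p and let-7f-5p fell 2.38-fold and 2.21-fold. The largest rise was that of miR-5110, from 2.14 ± 0.0651 to 13.7 ± 0.258, or 6.40-fold. Of 582 miRNAs measured on both arrays, 25 rose at least 2-fold and 62 fell at least 2-fold, each by more than 2 standard errors over spots, and 495 stayed within these bounds.

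The 2 largest falls were in the miR-15/16 family, which restrains the cell cycle. miR-503-5p (chromosome X, 50407174 to 50407188, mm9) fell 5.01-fold and its neighbour miR-322-5p (chromosome X, 50407455 to 50407475) 4.97-fold, while miR-497a-5p and miR-195a-5p both fell 3.83-fold. In the software's own total per miRNA, which for these 3 also held the listed total of another miRNA, the log2 differences of miR-503-5p, miR-497a-5p and miR-195a-5p were 0.10, 3.95 and 1.38. In all, 6 of the 7 family members measured on both arrays fell. miR-146a-5p, which dampens inflammatory signalling, fell 4.39-fold, miR-27b-3p and miR-23b-3p, which lie side by side on chromosome 13 (63402073 to 63402088 and 63401842 to 63401857), both fell 4.03-fold, and miR-26a-5p fell 3.93-fold. After miR-5110 the largest rises were those of miR-5132-5p at 2.81-fold, miR-466i-5p at 2.45-fold, miR-6956-5p and miR-6945-5p at 2.44-fold, miR-3082-5p at 2.37-fold, miR-3154 at 2.29-fold, miR-8109 and miR-7654-3p at 2.25-fold and miR-1187 at 2.21-fold. With hybridization spike-in scaling these 9 stood at log2 differences from 0.64 for miR-5132-5p to 0.29 for miR-1187, short of the 2-fold rule, and miR-5110 alone passed it. Of the 25 that rose, 16 were numbered 3000 or above, and of the 62 that fell, 0 were. Detected in N-Exo alone, miR-145a-5p, the smooth muscle partner of miR-143, was at least 4.01-fold lower in H-Exo, miR-148a-3p at least 3.91-fold, miR-9-3p at least 3.29-fold, miR-181a-5p at least 3.03-fold and miR-467e-5p at least 2.69-fold. Detected in H-Exo alone, miR-760-5p was at least 2.06-fold higher and miR-666-5p at least 2.02-fold higher under the main scaling. Before scaling they read 21.9 and 21.7 in H-Exo against 18.7 and 19.0 in N-Exo, so these 2 bounds came with the scaling.

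A list's median runs over its members detected on at least 1 of the 2 arrays, with an undetected side at the floor, while the counts of higher and lower members are out of those measured on both. Among the fixed lists, 13 of 21 mesenchymal and fibroblast miRNAs measured on both arrays fell and 0 rose. The list's median log2 difference was -1.26, below those of all 10000 random lists matched on signal, and -1.60 relative to all measured miRNAs. The hypoxia-responsive list, drawn up from miRNAs described as induced by hypoxia in cells, had 10 of 16 members lower and 0 higher, with a median of -1.05 and falls in miR-23b-3p, miR-26a-5p, miR-195a-5p and miR-30b-5p, the last by 2.83-fold. Bone, cartilage and fat differentiation miRNAs had 9 of 14 lower (median -1.21), among them miR-196a-5p by 2.73-fold and miR-140-5p, a cartilage miRNA, by 2.71-fold. Cardiac protection or repair miRNAs had 7 of 17 lower (median -0.93), with miR-199a-3p at 3.53-fold, miR-199a-5p at 3.25-fold and miR-214-3p at 2.59-fold. The medians were -1.59 for the miR-15/16 family, -1.12 for the miR-232724 clusters with 4 of 6 lower, -0.86 for let-7 with 5 of 11 lower, -0.93 for miR-30 with 4 of 8 lower (miR-30c-5p 3.57-fold, miR-30e-5p 3.24-fold) and -0.87 for miR-29, of which miR-29c-3p fell 2.57-fold. Inflammation-linked miRNAs (median -0.97) had 3 of 10 lower, among them miR-146b-5p by 2.81-fold, angiogenesis-related ones (-0.44) 6 of 22, such as miR-130a-3p by 2.45-fold and miR-15a-5p by 2.37-fold, and p53-linked ones (-0.72) 2 of 5, miR-22-3p (log2 difference -1.32) and miR-107-3p (-1.09). None of the 14 measured members of the growth-promoting miR-17~92 cluster and its paralogues passed the rule (median -0.21). These 13 medians were below 0 under each of the 7 scalings tried.

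The Dlk1-Dio3 imprinted cluster had a median of 0.46 with 0 of 9 members past the rule, the Sfmbt2 intron cluster 0.38 with miR-466i-5p higher and miR-467a-3p, miR-467b-5p and miR-466b-3p lower out of 20, and the pluripotency clusters 0.23 with 0 of 7. Each of these 3 medians turned below 0 with hybridization spike-in scaling. Markers of other cells were few. By the detection rule used here the probes of endothelial miR-126 were not well above background on any array. The software's own probe totals for miR-126a-3p summed to 3.74 in H+G-Exo, where its listed total also held that of another miRNA. No member of the blood cell (median 0.15, 4 measured), muscle and heart (0.0005, 2 measured) or neuron list (-0.21, 3 measured) passed the rule. The epithelial list (-0.16) had miR-200b-5p 2.10-fold higher, and the list of serum and liver miRNAs, kept for the bovine serum of the medium, (0.24) had miR-193b-5p 2.16-fold higher. The blood, muscle and heart, and serum medians also turned below 0 under some scalings. The technical list of GC-rich miRNAs had a median of 0.62 with miR-5130, miR-762 and miR-1224-5p higher, and the list of miRNAs numbered 3000 or above had 0.40 (0.44 over its 297 members measured on both arrays), and both list medians turned below 0 under some scalings. Across the 582 measured miRNAs the log2 difference rose with the GC content of the probe (Spearman's rho 0.44, across miRNAs, which are not independent replicates). The share of higher calls was 28.7% here, against 6.74% with the 75th percentile over all probes, 16.7% with the median, 22.4% with quantile normalization, 0.741% without scaling, 1.98% with labelling spike-ins and 0.730% with hybridization spike-ins.

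The second comparison, of H+G-Exo with H-Exo, asked what GW4869 changed under hypoxia. miR-210-3p fell 2.14-fold, the largest value of the 7 scalings. It was 2.07-fold lower with quantile normalization, and short of the 2-fold rule with the 75th percentile over all probes (1.70-fold), the median (1.61-fold), the labelling spike-ins (1.34-fold), the hybridization spike-ins (1.15-fold) and no scaling (1.07-fold). miR-125a-5p, which belongs with miR-125b to the lin-4 family, fell 4.77-fold, from 3.40 ± 0.179 to 0.713 ± 0.0301, and miR-29b-3p, a repressor of collagens, fell 3.98-fold, from 3.96 ± 0.0603 to 0.996 ± 0.0257. miR-494-3p of the Dlk1-Dio3 cluster (chromosome 12, 110953586 to 110953598, mm9) rose 4.86-fold, from 5.12 ± 0.268 to 24.9 ± 0.496, and the related miR-3473b and miR-3473a rose 6.95-fold and 6.77-fold. Of 566 miRNAs measured on both arrays, 35 rose and 148 fell, and the median miRNA fell by 0.42 on the log2 scale.

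The other large rises were those of miR-7058-5p at 5.89-fold, miR-6360 at 4.23-fold, miR-2137 at 4.21-fold, miR-8117 at 3.93-fold, miR-6934-5p at 3.88-fold, miR-423-3p, common in serum, at 3.83-fold and miR-5121 at 3.76-fold. The other large falls were those of miR-7078-5p at 4.99-fold, miR-5100 at 4.47-fold, miR-1943-5p at 4.10-fold, miR-5134-5p at 4.05-fold, miR-487b-3p and miR-6390 at 3.99-fold, miR-300-3p at 3.93-fold and miR-96-5p at 3.92-fold. Spots varied widely for some of these. miR-1943-5p read 5.20 ± 1.66 in H-Exo and 1.27 ± 0.404 in H+G-Exo. miR-6390 read 0.330 ± 0.134 and 0.0826 ± 0.0333, the last close to the floor. Without scaling the 10 largest falls stood at log2 differences from -1.32 for miR-7078-5p to -0.97 for miR-96-5p. Detected with GW4869 only, miR-125b-1-3p was at least 6.20-fold higher, miR-7681-3p 3.06-fold, miR-7085-5p 3.05-fold, miR-7219-5p 3.02-fold and miR-677-3p 2.81-fold, each as a lower bound. Detected without it only, miR-6412 was at least 4.61-fold lower in H+G-Exo, miR-666-3p 3.60-fold, miR-346-5p 3.32-fold, miR-466b-3p 3.10-fold and miR-467b-5p 3.06-fold, all under the main scaling. Before scaling the gaps were smaller, such as 40.8 in H-Exo against 17.6 in H+G-Exo for miR-6412 and 30.1 against 18.1 for miR-346-5p.

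The falls reached across the fixed lists and beyond them. Of the 274 measured miRNAs numbered below 3000, 13 rose and 107 fell, with a median of -0.73. The lists of this paragraph hold such miRNAs and share members, so their falls are not separate results. Among let-7 members 9 of 11 fell (median -1.23), led by let-7e-5p at 3.44-fold and let-7d-5p at 3.37-fold. Of the 13 measured miR-17~92 members 7 fell (median -1.01), with miR-19a-3p at 3.22-fold, miR-18a-5p at 3.19-fold and miR-20a-5p at 2.80-fold. The mesenchymal list had 13 of 21 lower (-1.16), the hypoxia-responsive list 10 of 16 (-1.15) with miR-103-3p at 3.62-fold, the angiogenesis list 11 of 21 (-0.98) with miR-15a-5p at 3.34-fold, and the cardiac list 9 of 16 (-0.98). All 3 measured miR-29 members fell (-1.58), as did 5 of 5 p53-linked miRNAs (-1.42), among them miR-34b-5p at 2.93-fold and miR-34a-5p at 2.87-fold, 4 of 6 of the miR-15/16 family (-1.17), 3 of 6 of the miR-232724 clusters (-1.17) and 3 of 5 epithelial miRNAs (-1.05). These 11 list medians stayed below 0 under each of the 7 scalings, but the main scaling gave the lowest value of each. Without scaling they were -0.24 for let-7, -0.14 for miR-17~92, -0.16 for the hypoxia-responsive list, -0.10 for the cardiac list and -0.05 for the epithelial list. The medians of the miR-30 family (-0.92, 4 of 8 lower), the inflammation-linked list (-0.51, 4 of 10 lower, miR-212-3p at 3.18-fold), the blood cell list (-0.54, 2 of 4 lower, miR-451a at 3.02-fold), the Sfmbt2 cluster (-0.83, 5 of 16 lower, miR-669d-3p at 3.59-fold) and the neuron list (-0.44, miR-212-3p of 3 lower) turned above 0 under some scalings, and that of bone, cartilage and fat miRNAs (-0.98, 9 of 14 lower, miR-143-3p at 2.57-fold) reached 0.

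The remaining lists split. In the Dlk1-Dio3 cluster miR-494-3p rose while miR-487b-3p, miR-300-3p and miR-541-5p were among the 4 of 9 that fell (median -0.02, and -0.49 over those 9). In the pluripotency clusters miR-292a-5p, an embryonic stem cell miRNA, rose 2.07-fold (median 0.18, and -0.11 over the 7 measured on both arrays). In the serum list miR-423-3p rose while miR-451a and miR-92a-3p fell, the last by 2.07-fold (median -0.09). In the GC-rich technical list miR-2137 and miR-1897-3p rose, the last 3.32-fold, and miR-5100, miR-6366 and miR-3963 fell, the last 3.70-fold (median -0.09). Neither muscle and heart miRNA passed the rule (median -0.26), and of 292 miRNAs numbered 3000 or above 22 rose and 41 fell, with a median of -0.20 over these 292 and of -0.02 over the list. The Dlk1-Dio3, serum, muscle and both technical medians turned above 0 under some scalings, and the pluripotency list median stayed above it. Here too the log2 difference rose with the GC content of the probe (rho 0.42 across the 566 miRNAs, 0.51 across the 274 numbered below 3000). Higher calls were 19.1% of all calls, against 41.9% with the 75th percentile over all probes, 48.5% with the median, 38.9% with quantile normalization, 96.4% without scaling, 78.9% with labelling spike-ins and 91.5% with hybridization spike-ins. Without scaling 185 miRNAs rose and 7 fell, so the balance of rises and falls in this comparison was set by the scaling.

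The third comparison set H+G-Exo against the normoxic N-Exo. miR-99a-5p and miR-23b-3p of the mesenchymal list and miR-322-5p of the miR-15/16 family were among the 10 largest falls. miR-322-5p fell 13.0-fold, from 4.15 ± 0.154 to 0.318 ± 0.0197, miR-99a-5p 12.6-fold, miR-23b-3p 12.6-fold, from 6.36 ± 0.185 to 0.505 ± 0.0290, and miR-21a-5p 6.40-fold, from 190.4 ± 15.4 to 29.7 ± 0.657. miR-7058-5p rose by 3.03 on the log2 scale, miR-2137 7.10-fold, from 7.63 ± 0.0902 to 54.2 ± 1.92, and miR-494-3p 4.79-fold. miR-210-3p was 1.22-fold lower in H+G-Exo, within the 2-fold rule, and its log2 difference of -0.28 turned to between 0.03 and 0.05 with the median, quantile and labelling spike-in scalings. Of 606 miRNAs measured on both arrays 111 rose and 158 fell, and the median difference was -0.05.

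Further large falls were those of miR-26a-5p at 12.3-fold, miR-27b-3p and miR-143-3p at 11.8-fold, miR-503-5p at 11.3-fold, miR-199b-5p at 10.4-fold and miR-30e-5p and miR-199a-3p at 10.3-fold. Further rises were those of miR-6360 at 6.16-fold, miR-423-3p at 5.52-fold, miR-5132-5p at 5.29-fold, miR-3077-5p at 5.21-fold, miR-6939-5p at 5.05-fold, miR-6934-5p at 4.91-fold and miR-598-5p at 4.54-fold. As lower bounds, miR-125b-1-3p was at least 8.97-fold higher in H+G-Exo, miR-7219-5p 4.36-fold, miR-294-5p 3.60-fold, miR-666-5p 3.33-fold and miR-7685-3p 3.31-fold. Not well above background in H+G-Exo, miR-374c-5p was at least 8.99-fold lower, miR-497a-5p 8.78-fold, miR-467b-5p 8.34-fold, miR-466b-3p 7.91-fold and miR-148a-3p 6.78-fold.

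Of the mesenchymal list 20 of 22 members fell (median -2.10, below all 10000 matched lists) and miR-125a-3p, named after its value was seen, rose with a log2 difference of 1.83. The medians of the cardiac, miR-15/16 and bone, cartilage and fat lists also lay below all their matched lists. The miR-15/16 family had 6 of 6 lower (median -2.61), miR-29 3 of 3 (-2.53), let-7 9 of 11 (-2.31), the miR-232724 clusters 5 of 6 (-2.32), p53-linked miRNAs 6 of 6 (-1.99), cardiac miRNAs 14 of 16 (-1.85), hypoxia-responsive miRNAs 13 of 16 (-1.73, and -2.64 over those 16), miR-30 6 of 8 (-1.68), angiogenesis-related miRNAs 14 of 21 (-1.47) and miR-17~92 9 of 13 (-1.19). Examples were let-7f-5p at 7.07-fold, miR-29c-3p at 7.69-fold, miR-22-3p at 6.20-fold, miR-103-3p at 7.45-fold, miR-30c-5p at 7.34-fold, miR-15a-5p at 7.91-fold and miR-19b-3p at 4.74-fold. Bone, cartilage and fat miRNAs had 11 of 15 lower and miR-135a-1-3p higher (-1.73), and inflammation-linked miRNAs 8 of 10 lower and miR-125a-3p again higher (-1.57). Among other cell types, 3 of 4 blood cell miRNAs (-1.10), 2 of 6 epithelial ones (-0.83, miR-96-5p at 6.30-fold), 1 of 4 neuronal ones (-0.68, miR-212-3p at 2.92-fold) and 0 of 4 muscle ones (-0.26) fell. All 17 medians of this paragraph stayed below 0 under each of the 7 scalings.

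The Sfmbt2 cluster had 6 of 16 lower and miR-466i-5p higher (median -0.35, below 0 under each scaling), with miR-467a-3p at 8.77-fold lower. The pluripotency clusters had 2 of 7 higher (0.41), miR-292a-5p at 3.12-fold and miR-291b-5p at 2.40-fold. The Dlk1-Dio3 cluster had 2 higher, miR-494-3p and miR-370-3p, and 4 lower of 8 (median 0, and -0.61 over those 8), and the serum list 2 higher, miR-423-3p and miR-193b-5p, and 2 lower of 8 (median 0). These last medians turned above 0 under some scalings. Of 20 GC-rich miRNAs 8 rose and 4 fell (0.88), and of 311 numbered 3000 or above 76 rose and 28 fell, with a median of 0.24 over these 311 and of 0.07 over the list. Of the 295 measured miRNAs numbered below 3000, 35 rose and 130 fell, with a median of -0.70. The log2 difference rose with the GC content of the probe (rho 0.49 across the 606 miRNAs). Higher calls were 41.3% of all calls, against 47.7% with the 75th percentile over all probes, 57.0% with the median, 51.1% with quantile normalization, 50% without scaling, 58.7% with labelling spike-ins and 43.9% with hybridization spike-ins.

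**Figure D2:**
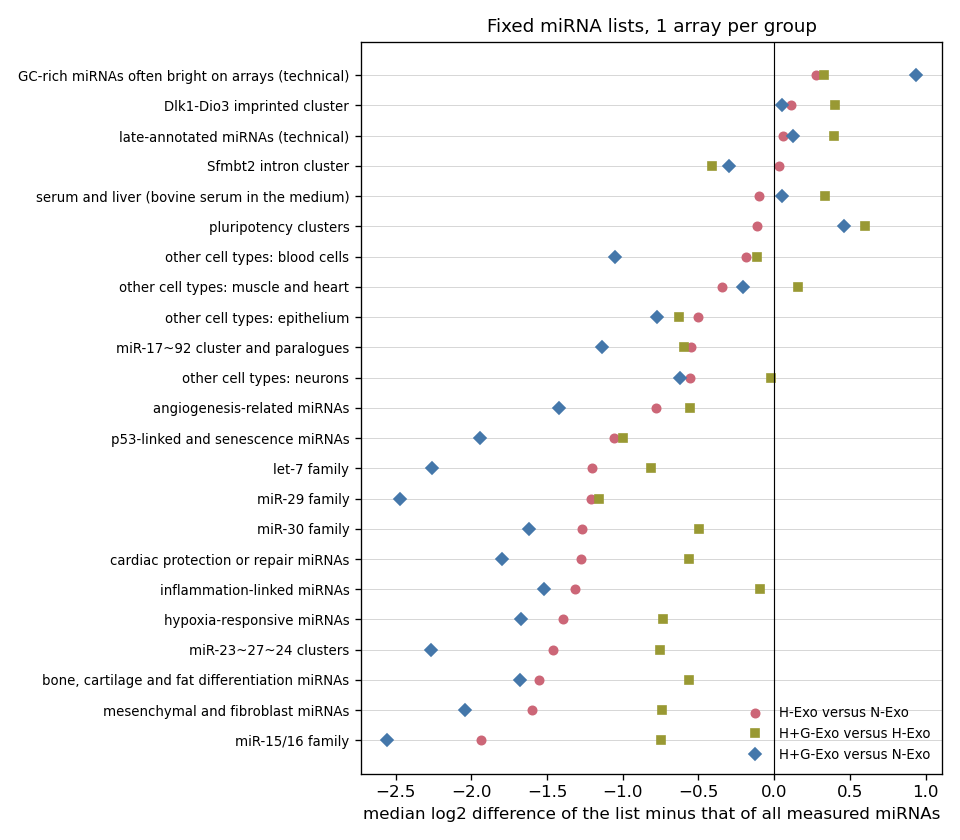
Median log2 difference of 23 fixed miRNA lists minus that of all measured miRNAs, for the 3 comparisons. Each symbol is 1 list in 1 comparison of 2 arrays. The miR-15/16 family (-1.93) and the mesenchymal list (-1.60) lay lowest in H-Exo against N-Exo, and every list from the angiogenesis list down lay lower still in H+G-Exo against N-Exo.

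GW4869 was then set against the changes seen with hypoxia. Of the 62 miRNAs that fell in H-Exo, 0 came back at least 2-fold with GW4869, 44 fell at least 2-fold further, 4 of them as a lower bound, and 18 did neither. The 44 depended on the scaling: 31 fell further with the 75th percentile over all probes, 26 with quantile normalization, 24 with the median, 9 with the labelling spike-ins, 4 with the hybridization spike-ins and 2 without scaling. miR-322-5p, miR-99a-5p, miR-143-3p and miR-23b-3p were among the 44, and 60 of the 62 were also at least 2-fold lower in H+G-Exo than in N-Exo, 4 of them as a lower bound. Of the 25 that rose in H-Exo, 5 came back at least 2-fold (miR-5110, miR-200b-5p, miR-5134-5p, miR-547-5p and miR-6945-5p, named after their values were seen), 0 rose further and 20 did neither. The comparisons share arrays. Over 562 miRNAs measured on all 3 arrays, the differences H-Exo minus N-Exo and H+G-Exo minus H-Exo correlated with r = 0.36 across miRNAs, where 50 simulated sets of unchanged arrays gave a mean of -0.48 over the same miRNAs, and their covariance was 0.228 against -0.00430 simulated. Without bounds, the lower calls of these comparisons shared 40 miRNAs, where independent lists would share 15.3. H-Exo minus N-Exo and H+G-Exo minus N-Exo correlated with r = 0.78 against 0.51 simulated, with a covariance of 0.736 against 0.00467, and shared 56 lower calls, where independent lists would share 16.1, and 13 higher calls against 4.76. The shared H-Exo array alone gave a value below 0 for the first pair, while part of the excess of the second pair may come from the shared N-Exo array. The independent lists drew on all 562 miRNAs alike. Yet all 62 lower calls in H-Exo against N-Exo, and 107 of 148 in H+G-Exo against H-Exo, were numbered below 3000. The simulated arrays differed by spot error only. Differences between arrays that go with this class or with GC content are in neither reference, so the excess was not separated from them. The 5 and 0 that came back changed with the scaling to 0 and 11 without any.

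**Figure D3:**
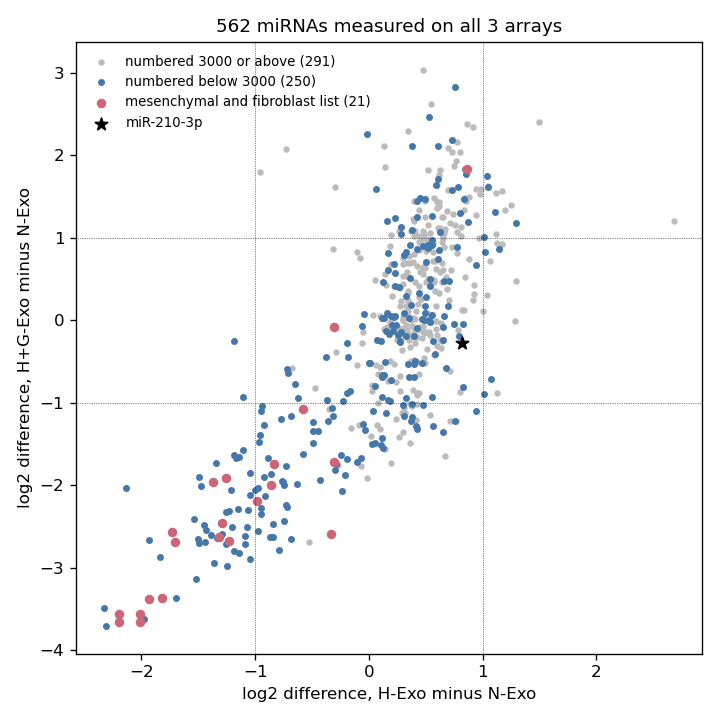
Log2 difference from N-Exo of 562 miRNAs measured on all 3 arrays, in H-Exo (horizontal axis) and in H+G-Exo (vertical axis), with dotted lines at 2-fold. Each point is 1 miRNA: 291 numbered 3000 or above, 250 others and 21 of the mesenchymal list. All but 1 of the mesenchymal points lay below 0 on both axes, and miR-210-3p stood at 0.82 and -0.28.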

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

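Both tests of this part were chosen only after the results were seen. A signal in values that the comparisons did not use drew attention: the software's listed total per miRNA, which is 0.1 where a miRNA was not detected. In H-Exo, 1 miRNA had a total over 100 with a total of 0.1 in N-Exo and no detected probe, miR-5625-5p with 157. In H+G-Exo 7 miRNAs did, among them miR-127-5p with 2248, and the difference between the groups was not tested.

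The pattern behind these values was a listed total more than 1.5 times the sum of the miRNA's own probes. Over the 3 arrays, 382 of 382 such totals, or 100%, exceeded the own probe sum by the listed total of the detected miRNA that precedes it in name order, within 0.1% of the listed total. Additions could chain: in H+G-Exo miR-127-5p held 2.32 of its own and the listed total of miR-126a-3p, itself 3.74 of its own and 2242 of miR-125b-5p. Cross-hybridization of the probes would enter the probe sum itself, so the match of the excess within that tolerance in 100% of cases argued against it. That count is the one just given and was known when this criterion was written, so it adds no separate support. Earlier versions of this second test, the first of them written before its result was seen, decided nothing. They gave a median spot signal of 36.9% of that of the preceding miRNA, and a median own probe sum of 12.6% of the listed total. No biological explanation was tested.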

How the results depend on the processing

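Scaling by the labelling spike-ins, scaling by the hybridization spike-ins and the recomputed total per miRNA were added after seeing the data, and the other 19 alternatives were planned. No paired analysis was possible because each group had 1 array. Of 1115 values of the 10 largest rises and falls of each comparison under the alternatives, 1112 kept their sign and 3 did not. These miRNAs were picked as the extremes of the same arrays. Some alternatives, such as leaving out the late-annotated miRNAs, left the value of a remaining miRNA as it was. A sign also counted as kept where little was left, such as 0.29 for miR-1187 in H-Exo against N-Exo with hybridization spike-in scaling. The kept signs therefore say little about how far the folds hold. Of 1300 list medians 141 moved by more than the members' SD, and 81 of 132 counts of calls stayed within 1.5 times. Of 132 counts of lower bounds 66 did. A floor 2 times higher, detection on all 3 arrays and no requirement on spot error moved none of the results below past these limits. The cause was not tested except where named. Low signal over background limits the undetected miRNAs, whose folds are lower bounds.

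In what follows, higher and lower are counts of miRNAs past the 2-fold rule, and miR-210-3p is its log2 difference. Back counts are miRNAs 2-fold higher, then 2-fold lower, in H-Exo that came 2-fold back with GW4869. Further counts are those that moved at least 2-fold further the same way, 0 of those higher and 44 of those lower with the main setting, and were counted only after the results were seen. With the 75th percentile over all probes, H-Exo against N-Exo had 6 higher and miR-210-3p at 0.60, H+G-Exo against H-Exo 70 higher, 97 lower and -0.77, H+G-Exo against N-Exo -0.17, back counts were 1 and 2, and 1 higher moved further. With the median these were 15 and 0.72, then 83, 88 and -0.69, then 0.0284, with 2 and 2 back and 1 and 24 further. With quantile normalization miR-210-3p was 1.105 in H-Exo against N-Exo and 0.052 in H+G-Exo against N-Exo, 68 were higher in H+G-Exo than in H-Exo, 2 of those lower in H-Exo came back, and 1 and 26 moved further. Without scaling H-Exo against N-Exo had 1 higher, 134 lower, miR-210-3p at -0.0115 and a mesenchymal median of -2.09, H+G-Exo against H-Exo 185 higher, 7 lower, -0.10 and 11 lists with a median below 0, H+G-Exo against N-Exo -0.11, 0 and 11 came back, and 2 lower moved further. With the labelling spike-ins H-Exo against N-Exo had 2 higher, 99 lower and 0.47, H+G-Exo against H-Exo 135 higher, 36 lower and -0.43, H+G-Exo against N-Exo 169 higher and 0.0434, 0 and 3 came back, and 1 and 9 moved further. With the hybridization spike-ins these were 1, 136 and -0.0335 with a mesenchymal median of -2.11, then 173, 16 and -0.20, with 0 and 8 back and 4 lower further.

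With normexp, H-Exo against N-Exo had 3 higher and 0.68, H+G-Exo against H-Exo 17 higher, 70 lower and -0.93, H+G-Exo against N-Exo 58 higher and 98 lower, 1 higher came back, and 21 lower moved further. Without background subtraction these were 6 and 0.71, then 18, 89 and -0.97, then 63 higher, with 1 back and 23 lower further. The mean over probes gave 15 higher in H-Exo, 2 of them back. The scanner total gave miR-210-3p 0.59 in H-Exo against N-Exo, 84 higher and -0.79 in H+G-Exo against H-Exo, 167 higher and -0.19 in H+G-Exo against N-Exo, 25 and 6 back, and 1 higher further. It reversed miR-503-5p to 0.10, miR-497a-5p to 3.95 and miR-195a-5p to 1.38, because another miRNA's listed total was added to theirs in H-Exo, and the recomputed total, without that addition, did not reverse them. The recomputed total gave 76 higher and -0.91, then 177 higher and -0.13, 3 and 2 back, and 1 higher further. The series table gave 0.92, then 81 higher and -0.68, then 185 higher and 0.24, 2 and 3 back, and 2 higher further. With the median over spots 2 higher moved further. Detection by all spots gave 15 higher in H-Exo, and 2 of those lower came back. No detection filter gave a mesenchymal median of -0.32 in H-Exo against N-Exo and 4, 6 and 6 lists below 0 in the 3 comparisons, as members at the floor on both arrays count as 0. With outlier spots kept, 3 higher came back. Without miRNAs numbered 3000 or above, 9, 13 and 35 were higher in the 3 comparisons, 2 came back, and 350.0, 288 and 319 were detected in N-Exo, H-Exo and H+G-Exo, since fewer miRNAs were counted. By construction the 1.5-fold threshold gave more, 137 higher and 101 lower, then 84 and 232, then 176 higher, with 41 and 3 back and 37 and 77 further, and the 3-fold threshold fewer, 1 and 16, then 12 and 48, then 41 and 98, with 0 higher back and 3 lower further.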

Other observations

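The tests of this part chosen only after the result was seen were those of scaling, of a lower yield and of miRNAs cut from one transcript. Several miRNAs listed in one hairpin cluster had like values in H-Exo against N-Exo. The log2 differences were -2.31 for miR-322-5p and -2.33 for miR-503-5p, -1.94 for both miR-195a-5p and miR-497a-5p, and -2.01 for both miR-23b-3p and miR-27b-3p, against -1.05 and -1.19 for the near-identical miR-23a-3p and miR-27a-3p of another chromosome. miR-15a-5p and miR-16-5p stood at -1.24 and -1.21. Other neighbours lay apart, such as miR-99a-5p at -2.20 and let-7c-5p at -1.06, or miR-30b-5p at -1.50 and miR-30d-5p at -0.49. In the miR-17~92 cluster miR-17-5p stood at 0.24, miR-92a-3p at 0.11, miR-20a-5p at -0.19 and miR-19a-3p at -0.74.

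The 5p and 3p arms of a hairpin were both measured for 63 hairpins in H+G-Exo against N-Exo. Of 9 with both arms called, 2 had opposite calls, and they are named after their values were seen. miR-125a-5p stood at -2.59 and miR-125a-3p at 1.83, with probes of 47.4% and 62.5% GC. miR-193b-5p stood at 1.304 and miR-193b-3p at -1.39, with probes of 57.1% and 64.7% GC. The GC-richer arm had the higher value in 35 of 58 hairpins with unequal GC, 35 of 51 in H-Exo against N-Exo and 29 of 47 in H+G-Exo against H-Exo.

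A hypothesis was that miRNAs cut from one transcript moved alike with hypoxia, with clusters taken from general knowledge and not checked against a genome: the miR-199a-3p probe, counted with miR-214-3p of chromosome 1, was placed on chromosome 2 by the array files. Over 35 pairs of 37 miRNAs in 15 clusters, the median absolute difference between members was 0.43, at percentile 3.2 of random assignments of miRNAs numbered below 3000, whose median was 0.81. When values were shuffled only among the 40 measured cluster members, 3 of them without a measured partner, it stood at percentile 0.94. Over the 13 pairs of 20 miRNAs whose probes the array files place at 1 position each and on 1 chromosome, the median was 0.44, at percentiles 9.74 of random assignments and 10.67 of shuffles among these 20. The hypothesis therefore stays open, as these pairs were few, near-identical probes and shared GC content were not removed, and it was found and tested on the same arrays.

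The lower level of mesenchymal miRNAs in H-Exo than in N-Exo was weighed against 4 explanations. Against scaling, the median stayed at -1.23 or lower under every scaling run, down to -2.11. In a linear fit of GC content and length of the probes, members lay -0.94 below the trend of the other miRNAs in the median (95% bootstrap interval over members -1.32 to -0.78). The fit pooled miRNAs numbered below 3000 with the later ones, and its GC slope was -0.019 log2 per 10 GC points. Among the 285 measured miRNAs numbered below 3000, to which the members belong, Spearman's rho with GC was 0.49. A GC effect within that class was therefore not excluded. For a lower yield of all long-annotated miRNAs alike, the miR-17~92 list lay 1.05 above the mesenchymal list (interval over members 0.50 to 1.66). That list was picked after its small fall (median -0.21) had been seen. Both intervals treated members as independent, though some are arms of the same hairpin, such as miR-31-5p and miR-31-3p. They cover the spread among members on these arrays, not that between samples. The miR-15/16 family (-1.59) and the bone, cartilage and fat list (-1.21) lay below or near the mesenchymal list (-1.26). The gap therefore shows only that these 2 lists differed on these arrays, and does not set the mesenchymal list apart. Hypoxia itself and a difference between samples cannot be told apart with 1 array per group, so an effect of hypoxia on these miRNAs stays a hypothesis.

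The higher miR-210-3p in H-Exo than in N-Exo depended on the scaling between the arrays. Its fold was 0.977 at the lowest and 2.15 at the highest of the scalings run, and scaling may account for the whole difference. miR-210-3p stood at percentile 93.3 of the 285 measured miRNAs numbered below 3000, with 18 above it. A uniform shift shared by all long-annotated miRNAs leaves ranks as they are, so it would not by itself give this rank. The rank cannot tell whether such a shift was also present. Without a replicate it also cannot be set apart from the spread among miRNAs. Among those 285 the difference rose with the GC content of the probe (Spearman's rho 0.49), and the miR-210-3p probe had 62.5% GC. Whether its rank goes with GC was not tested. An effect of hypoxia on miR-210-3p stays open and was not tested beyond this, with 1 array per group.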
